A study of Homo sapiens with 8 samples.

How the data were processed

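The measurement was bulk RNA-seq of human pluripotent stem cell derived cultures on day 5 of differentiation, in 8 samples. Per the labels' protocols, libraries were made from total RNA with an Illumina TruSeq RNA kit. The extraction text in the labels names a tissue other than these cultures, and nothing was taken from it. Reads had been processed with FastQC 0.11.9, cutadapt 1.18, STAR 2.7.9, HTSeq 0.10.0 and DESeq2 1.30.1 on the GRCh38 build, per the submitters' processing notes. Those notes give no order or settings, and the strand setting and annotation release are not given in the sources used here. Reads of a gene and an overlapping or antisense gene can therefore not be told apart.

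The authors deposited raw counts per Ensembl gene, per the file headers and the values, which were whole numbers with a different sum in each column. One table held the 4 sorted samples and another the 4 samples of the lines, and every column matched 1 sample. Both tables used here ended in an incomplete line, which was left out, and covered only part of the genes: 3555 in the sorted table, 99.1% of them protein coding, and 24484 in the other. The sums per library over all genes of a table were 2038386 to 2352275 and 8731970 to 10332886. In the edgeR fits the library sizes were taken over the genes left by the filter for low counts. Because the sorted table ended at an early identifier, the first sum is not the depth of the libraries. Gene symbols were found for 3555 and 24474 identifiers in a table of gene names. Coordinates and gene types came from GENCODE release 29 on GRCh38, in which every identifier was found.

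Samples were grouped by their titles into PEAR1-positive, PEAR1-negative, BC1 and PEAR1 knockout, with 2 samples each. Nothing in the labels says that the samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Replicate counts were compared by a chi-square test over genes with at least 10 counts. The statistic per degree of freedom was 1.75 and 1.91 in the sorted pairs, 2.04 in the knockout-labelled pair and 26.3 in the BC1 pair, all above sampling noise, and each library counted as its own replicate.

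The tests, groups, gene lists, alternatives and the rule for named genes were fixed before the data were examined. Each comparison was fitted to its own 4 libraries with edgeR 4.0.16 in R 4.3.3: filterByExpr by group, TMM normalisation and the quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjusted p below 0.05 and no fold minimum. Levels are TMM-normalised CPM, and the SE of a log2 fold change comes from the fitted model. A gene at 0 in both libraries of a group has a bound set against 3 counts over the group. A gene with 1 to 3 counts over a group has the ratio of summed counts with a Clopper-Pearson 95% interval. Bounds and intervals cover counting error only.

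The 28 fixed gene lists of cell types and pathways were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, where at least 3 members were tested. Numbers of list members in the text are those past the expression filter. That gave 17 lists in the sorted cells and 27 in the lines, and p-values were adjusted over the lists. A further list of 11 housekeeping genes, 3 of them in the sorted table, served only for scaling; with TMM, 4 of the 11 fell between the lines. Overlap of the comparisons was tested with Fisher's exact test for each pair of directions and adjusted over the 4 tests. Named genes were PEAR1, the 6 largest rises and 6 largest falls among called genes with a mean log2 CPM of at least 3 and groups that did not overlap, leaving out clone, non-coding, pseudogene and sex-chromosome marker names. To these came, from each of at most 10 lists with the smallest set-test p, the 2 called members with the largest change in the direction of the list and the 1 with the largest in the other direction, and up to 2 members of other lists.

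On simulated counts with the means and library sizes of the sorted cells (2943 genes), edgeR recovered 56% of genes changed 1.25-fold, 80% at 1.5-fold, 94% at 2-fold and 100% at 4-fold, with 2 false calls. For the lines (13281 genes) the shares were 4%, 16%, 62% and 100%, also with 2 false calls. Each simulated gene had the same dispersion in both groups, although the BC1 pair differed more than the knockout-labelled pair. At each fold 50 genes were changed, far fewer than were called in the data. These rates therefore do not cover the unequal spread of the lines or so many changed genes. In both comparisons, a list raised 2-fold was found by camera with the preset correlation and 0 other lists were called. The simulated genes were drawn independently of each other, so this cannot show how the preset correlation fares with correlated members. With an estimated correlation the raised list was missed (adjusted p = 0.264 and 0.12). No larger change and no other number of libraries was simulated, so the power of that setting beyond this case was not measured.

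Alternatives were DESeq2 1.42.0, RLE size factors, library size, housekeeping scaling, no filter or a CPM of at least 1 in 2 samples, a log2 fold minimum of 1, the replicate number as a block, each library left out, an estimated correlation, and fry. Added after seeing the data were a correction of each library for GC content and transcript length by splines with 5 degrees of freedom, a crossed pairing, a fit to the genes held in both tables and housekeeping scaling of the overlap.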

Results

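RNA was sequenced from cultures of human pluripotent stem cells on day 5 of differentiation toward blood. The study centres on PEAR1, platelet endothelial aggregation receptor 1, a membrane receptor with EGF-like repeats that is known from platelets and endothelium. In one experiment the cells were sorted into a PEAR1-positive and a PEAR1-negative population. In the other, unsorted cells of BC1, a human induced pluripotent stem cell line, were set beside cells labelled as a PEAR1 knockout made in BC1. The 8 samples formed 4 groups of 2, and the experiments shared no libraries.

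The counts of the sorted cells used here covered 3555 genes, in rising order of Ensembl identifier up to ENSG00000108587. Their totals were 2038386 and 2137250 in PEAR1-positive cells and 2086422 and 2352275 in PEAR1-negative cells. The counts of the lines covered 24484 genes, with totals of 10332886 and 8852605 in BC1 and 9190292 and 8731970 in the knockout-labelled libraries. Each total is the sum over the genes of its table, so that of the sorted cells is not a full library depth. In the lines, the genes that the sorted table also held took between 24.4% and 25.1% of the counts. Of these genes 43.7% were called between the lines, and of the later identifiers 43.8%. Genes beyond the last identifier of each table were not analysed here.

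PEAR1 itself (ENSG00000187800, chromosome 1, 156893698 to 156916434 in GRCh38) was the first gene examined. It had 879 and 1082 counts in BC1 and 1047 and 1032 in the knockout-labelled libraries. The level was 108.2 ± 28.8 CPM (SD, n = 2) in BC1 and 111.6 ± 2.68 CPM (SD, n = 2) in the knockout-labelled libraries. The log2 difference of 0.05 ± 0.20 (SE) did not pass the test (edgeR adjusted p = 0.871). It was 0.34 without BC1 replicate 2 (adjusted p = 0.000311) and -0.18 without BC1 replicate 1 (adjusted p = 0.0563). The transcript was therefore not lower under the knockout label, and a count over the whole gene cannot show a short edit or the protein. The group is called knockout-labelled throughout, and each direction below refers to that label. PEAR1 was not analysed here in the sorted cells.

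The first comparison asked how cells with PEAR1 on their surface differed from cells without it. The tested blood-forming transcription factors and most tested myeloid genes were higher in the PEAR1-positive cells. The tested HOXA genes and most tested lateral plate, mesenchymal and matrix genes were lower in them. GATA1, a transcription factor of erythroid and megakaryocytic cells, stood at 304.1 ± 42.96 CPM in PEAR1-positive cells and 30.4 ± 4.25 CPM in PEAR1-negative cells (SD, n = 2 each). This was a 10-fold rise (log2 3.33 ± 0.15 SE, adjusted p = 1.19e-142). EVX1, a homeobox gene of the primitive streak, was 13.2-fold lower in PEAR1-positive cells, at 4.27 ± 0.52 CPM against 57.0 ± 1.81 CPM (SD, n = 2 each, adjusted p = 2.76e-32).

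Of 2943 genes tested, 773 were higher and 762 lower in PEAR1-positive cells. Rises and falls were ranked among called genes by the rule for named genes, which asks a mean log2 CPM of at least 3. The 6 largest rises were those of TMEM40, CD84, FGR, SCGN, GATA1 and ASIC4. TMEM40, a transmembrane protein gene, rose 14.1-fold (log2 3.82 ± 0.39 SE). CD84, a receptor of the SLAM family on blood cells, rose 13.3-fold (log2 3.73 ± 0.74 SE), and FGR, a SRC-family kinase of myeloid cells, 12.6-fold (log2 3.65 ± 0.82 SE). SCGN, a calcium-binding protein, rose 11.5-fold and ASIC4, of the acid-sensing ion channel family, 9.38-fold. The 6 largest falls in that ranking were those of EVX1, HGF, HOXA3, LRP2, C5 and PITX3. HGF, hepatocyte growth factor, was 7.94-fold lower (log2 -2.99 ± 0.25 SE), and the endocytic receptor gene LRP2 6.21-fold lower (log2 -2.63 ± 0.20 SE). Complement component C5 was 5.95-fold lower and the homeobox gene PITX3 5.78-fold lower.

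The sorted table held 5 of the 20 blood-forming transcription factors of the list, and all 5 rose, by a median log2 of 2.69 (adjusted over the list alone, also 5). Besides GATA1, the largest was KLF1, an erythroid factor, at 8.22-fold (log2 3.04 ± 0.17 SE). As a set they gave adjusted p = 0.00185, and adjusted p = 0.313 with an estimated correlation. Of 6 myeloid and pan-leukocyte genes 5 rose and 1, CTSG, did not pass (adjusted over the list alone, also 5). TYROBP, an adaptor of innate immune receptors, rose 8.17-fold and CD33, a sialic acid binding lectin of myeloid cells, 5.06-fold. The myeloid list had a set test adjusted p = 0.00267, and adjusted p = 0.313 with an estimated correlation. Of 4 blood progenitor surface genes 3 rose and 1 fell. ITGA2B, the platelet integrin CD41, went from 247.8 ± 3.25 CPM to 2147 ± 56.5 CPM (SD, n = 2 each), an 8.66-fold rise. That list did not pass the set test (adjusted p = 0.0963), nor did the erythroid list (adjusted p = 0.214), of which ANK1, the red cell ankyrin, and KLF1 rose while 1 member fell. Both tested megakaryocyte genes rose, ITGA2B and the platelet tubulin TUBB1, the latter 2.92-fold.

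The 8 tested HOXA genes on chromosome 7 all fell in PEAR1-positive cells, by a median log2 of -2.20 (adjusted over the list alone, also 8). HOXA3 was 7.30-fold lower (log2 -2.87 ± 0.32 SE). HOXA2, with 1 and 3 counts in PEAR1-positive and 23 and 30 in PEAR1-negative cells, was also lower (log2 -3.58 ± 0.92 SE). The set test gave adjusted p = 0.000184, and adjusted p = 0.313 with an estimated correlation. Of 5 lateral plate and cardiac genes 3 fell and 2 did not pass, ISL1 by 4.72-fold and the atrial light chain MYL7 by 3.73-fold (set test adjusted p = 0.0289, and adjusted p = 0.317 with an estimated correlation). All 3 mesenchymal genes fell. ACTA2, smooth muscle actin, and the light chain MYL9 were each 2.23-fold lower (set test adjusted p = 0.0226, and adjusted p = 0.313 with an estimated correlation). Of 4 matrix genes 3 fell and 1, LAMB1, did not pass. The proteoglycan VCAN was 2.53-fold lower and the laminin LAMA1 1.92-fold (set test adjusted p = 0.026, and adjusted p = 0.385 with an estimated correlation). In these 3 lists the counts adjusted over the list alone were also 3, 3 and 3.

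Of 7 cell cycle genes 5 fell and 2 did not pass (adjusted over the list alone, also 5). The members that fell belong to DNA replication licensing, such as MCM6 (1.72-fold lower), and to the entry into S phase, such as E2F1 (1.57-fold lower). Tested as a set, the list gave adjusted p = 0.00776, and adjusted p = 0.313 with an estimated correlation. All 5 genes of the p53 and cell death list rose (adjusted over the list alone, also 5), among them the death receptor FAS at 1.74-fold and BBC3, which encodes PUMA, at 1.64-fold. The set test gave adjusted p = 0.0226, and adjusted p = 0.313 with an estimated correlation.

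The other tested lists did not pass. Of 5 endothelial genes 4 rose and ETV2 fell (adjusted p = 0.0556), with the angiopoietin co-receptor TIE1 at 2.21-fold and FLT4, VEGF receptor 3, at 1.87-fold. Of 4 epithelial genes 3 fell (adjusted p = 0.0517), with the desmosomal DSP 2.34-fold lower and the cadherin CDH3 2.31-fold lower. Of 3 BMP and TGF-beta targets 2 fell (adjusted p = 0.0556), among them BAMBI by 1.93-fold. The arterial list had 2 members up and 2 down (adjusted p = 0.94), with SEMA3G 1.84-fold higher and the Notch ligand JAG1 2.06-fold lower. The Notch list also had 2 up and 2 down (adjusted p = 0.967), and its median of 0.05 and mean of 0.21 were above 0 while its set test pointed down. MFNG, a glycosyltransferase that modifies Notch, rose 3.54-fold. Of 4 EGF-repeat genes related to PEAR1, 2 rose and 1 fell (adjusted p = 0.368; adjusted over the list alone, 2 rose and 2 fell). The scavenger receptors STAB1 and SCARF1 rose 3.44-fold and 2.58-fold. Of 3 hypoxia and glycolysis genes only ENO1 passed, 1.16-fold lower (adjusted p = 0.771). Lists with 1 or 2 members past the expression filter were not tested as sets. Among these, DNMT3B rose 1.73-fold and SALL4 was 1.58-fold lower, both of the pluripotency list, the WNT inhibitor DKK1 was 4.41-fold lower, STMN2 of the neural list 2.84-fold lower, and HOXB6 1.55-fold lower.

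For this comparison no list passed with an estimated correlation, and the smallest adjusted p was then 0.313. Scaling to the housekeeping genes, of which the sorted table held only 3, moved the share of higher genes among the calls from 50.4% to 38.5%, and the matrix, lateral plate and p53 lists were lost (adjusted p = 0.0831, 0.0911 and 0.119) under a correction for GC content and length, chosen after seeing the data.

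**Figure D1:**
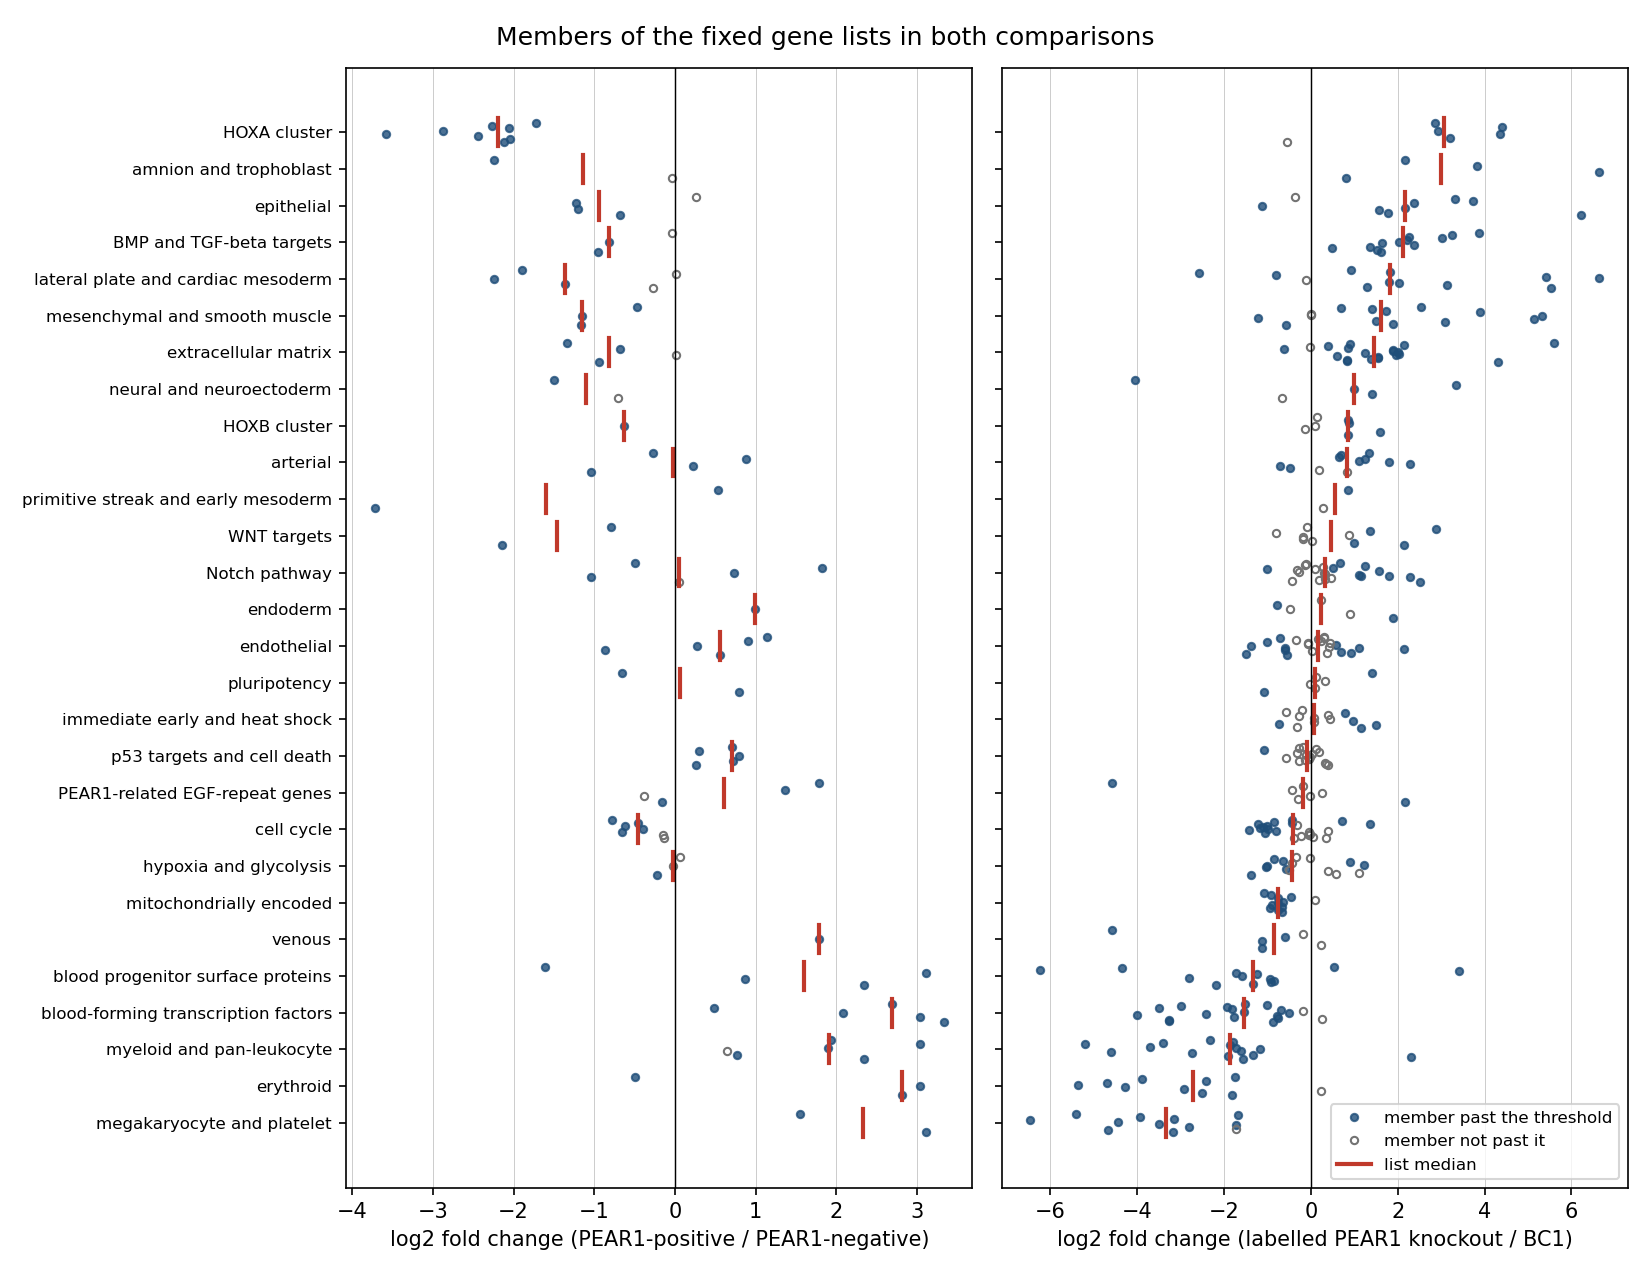
Each point is one tested gene of a fixed list, placed by its log2 fold change between the sorted populations (left) or between the lines (right); filled points passed the adjusted p threshold of 0.05, open points did not, and red bars mark list medians. Genes at 0 in one group sit at the bound set by 3 counts. The medians of the blood lists lie above 0 on the left and below 0 on the right, and the HOXA list, with medians of -2.20 and 3.06, lies the other way round.

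The second comparison asked how day-5 cells labelled PEAR1 knockout differed from those of BC1. Most tested genes of the blood lineages were lower in the knockout-labelled libraries, and most tested genes of mesenchyme, extracellular matrix, lateral plate mesoderm and BMP signalling were higher. IKZF1, the lymphoid and myeloid factor Ikaros, stood at 114.4 ± 24.7 CPM in BC1 and 7.13 ± 0.14 CPM in the knockout-labelled libraries (SD, n = 2 each). It was thus 16.0-fold lower (log2 -4.00 ± 0.21 SE, adjusted p = 2.5e-05). COL3A1, a fibrillar collagen, went from 48.7 ± 4.93 CPM to 1712 ± 12.2 CPM (SD, n = 2 each), a 35.2-fold rise (log2 5.14 ± 0.14 SE, adjusted p = 9.85e-06).

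Of 13281 genes tested, 2953 were higher and 2859 lower in the knockout-labelled libraries. The ranking again took called genes with a mean log2 CPM of at least 3. The 6 largest rises were those of CDX2, ANO1, PTH1R, HOXC8, CRABP2 and FIBIN. CDX2, a homeobox gene of posterior identity and trophectoderm, had 0 and 2 counts in BC1 and 316 and 261 under the knockout label, a ratio of 285 with a 95% counting interval of 78.6 to 2360. The ratios were 264 (72.7 to 2180) for the chloride channel ANO1, 197 (54.2 to 1630) for the parathyroid hormone receptor PTH1R, 139 (47.4 to 678) for HOXC8 and 111 (37.7 to 541) for FIBIN. The fitted log2 difference of FIBIN, 6.69, was 10.36 without BC1 replicate 1. CRABP2, which carries retinoic acid to the nucleus, rose 103-fold (log2 6.69 ± 0.41 SE). The 6 largest falls in that ranking were those of TSPYL5, CD84, F13A1, CASS4, PLEK and PTPRC. TSPYL5 had 248 and 167 counts in BC1 and 0 in both knockout-labelled libraries, at least 140-fold lower against 3 counts over the group. CD84 had 722 and 530 counts in BC1 and 4 and 0 under the knockout label. Its fitted log2 difference of -8.21 ± 0.84 (SE) rested on the 4 counts of knockout-labelled replicate 1. F13A1, coagulation factor XIII A, was lower by a ratio of 250 (68.8 to 2070), and the adaptor gene CASS4 97.1-fold lower. PTPRC, which encodes the leukocyte antigen CD45, had 167 and 150 counts in BC1 and 0 and 4 under the knockout label. Its fitted log2 difference was -6.24 ± 0.88 (SE), and -10.33 without knockout-labelled replicate 2.

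Among the megakaryocyte and platelet genes 11 of 12 fell and 1, GP9, did not pass (adjusted over the list alone, 12 fell). PLEK, pleckstrin, was 88.5-fold lower (log2 -6.46 ± 0.24 SE). PF4, platelet factor 4, had 31 and 34 counts in BC1 and 0 in both knockout-labelled libraries, at least 21.9-fold lower; it shares sequence with PF4V1, so the split of reads between the copies is uncertain. The list's median was -3.34 (set test adjusted p = 2.16e-07, and adjusted p = 0.251 with an estimated correlation). Of 15 myeloid and pan-leukocyte genes 14 fell and 1 rose (adjusted over the list alone, also 14 and 1). MPO, myeloperoxidase, was at least 36.8-fold lower, and CSF1R, the receptor of macrophage colony-stimulating factor, 24.4-fold lower (log2 -4.61 ± 0.22 SE). AZU1, the one that rose, had 1 and 6 counts in BC1 and 15 and 21 under the knockout label. Its log2 difference of 2.30 ± 0.78 (SE) was 1.45 without BC1 replicate 1 (adjusted p = 0.0888) and 4.10 without BC1 replicate 2. It was 1.99 without knockout-labelled replicate 2 (adjusted p = 0.145) and did not pass with DESeq2 (adjusted p = 0.0929). The list gave adjusted p = 5.47e-07, and adjusted p = 0.251 with an estimated correlation.

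Of 19 blood-forming transcription factors 17 fell and 2, MECOM and GATA2, did not pass (adjusted over the list alone, also 17). NFE2, a factor of platelet and erythroid genes, was 11.4-fold lower (log2 -3.51 ± 0.17 SE). RUNX1, which is required for blood to arise from endothelium and was singled out after its values were seen, had a log2 difference of -1.94 ± 0.14 (SE, adjusted p = 7.82e-05). The list's median was -1.54 (set test adjusted p = 5.47e-07, and adjusted p = 0.251 with an estimated correlation). Of 10 erythroid genes 9 fell and 1, EPOR, did not pass (adjusted over the list alone, also 9). HBA1, an alpha globin with a near-identical copy and so of uncertain read assignment, was at least 41.5-fold lower, and HEMGN at least 26.0-fold lower. The erythroid median was -2.72 (set test adjusted p = 1.95e-05, and adjusted p = 0.251 with an estimated correlation). All 13 blood progenitor surface genes changed, 11 down and 2 up (adjusted over the list alone, also 11 and 2). SPN, the sialomucin CD43 that marks early blood progenitors, was 20.4-fold lower (log2 -4.36 ± 0.16 SE). PROM1, which encodes CD133, rose 10.6-fold (log2 3.40 ± 0.25 SE). The set test gave adjusted p = 0.000488, and adjusted p = 0.251 with an estimated correlation.

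**Figure D2:**
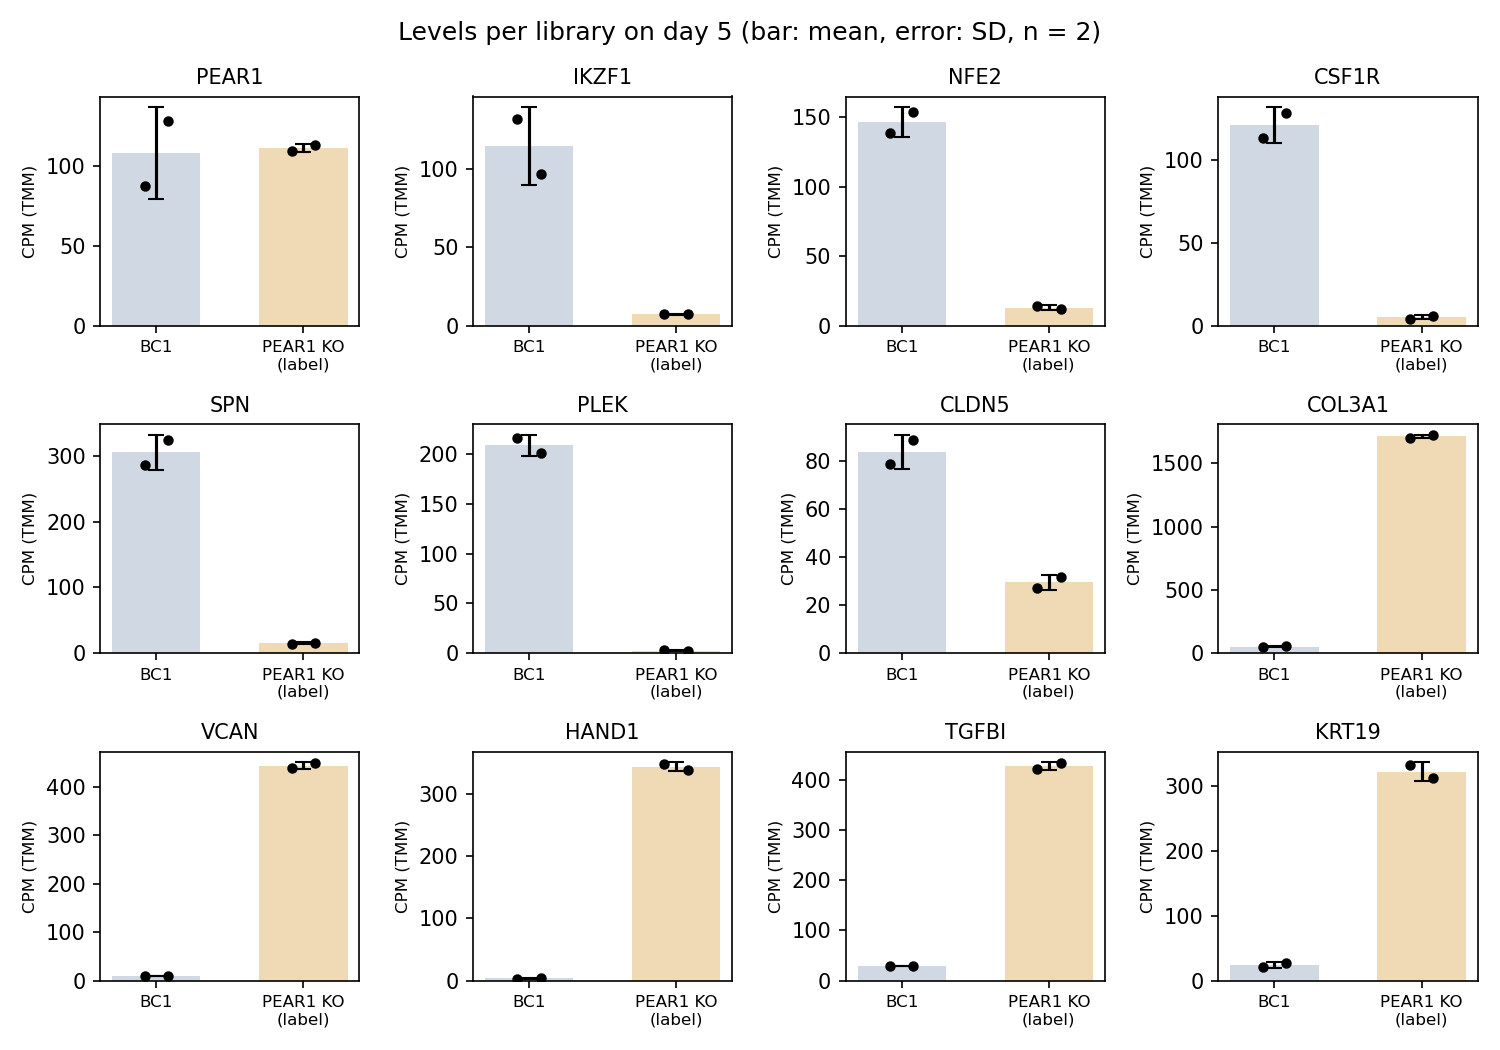
Bars show the mean level of 12 named genes in TMM-normalised CPM in BC1 and in the knockout-labelled libraries on day 5, error bars the SD of 2 libraries, and points each library. PEAR1 stands at 108.2 and 111.6, while IKZF1 falls from 114.4 to 7.13 and VCAN rises from 9.17 to 443.9.

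All 12 BMP and TGF-beta targets rose under the knockout label, by a median log2 of 2.13 (adjusted over the list alone, also 12). TGFBI, a matrix protein induced by TGF-beta, rose 14.6-fold (log2 3.87 ± 0.14 SE), and the inhibitory SMAD7 9.56-fold (log2 3.26 ± 0.19 SE). The set test gave adjusted p = 5.47e-07, and adjusted p = 0.251 with an estimated correlation. Of 20 matrix genes 18 rose, 1 fell and 1, LAMC1, did not pass (adjusted over the list alone, also 18 and 1). VCAN rose 48.4-fold (log2 5.60 ± 0.15 SE) and COL12A1 19.7-fold (log2 4.30 ± 0.39 SE). LAMA4 fell by 0.61 on the log2 scale (adjusted p = 0.0231), a call that was lost without either knockout-labelled library (adjusted p = 0.248 and 0.269), with DESeq2 and under 2 other scalings. The list gave adjusted p = 5.47e-07, and adjusted p = 0.257 with an estimated correlation. Of 14 mesenchymal and smooth muscle genes 10 rose and 2 fell (adjusted over the list alone, also 10 and 2). LUM, the proteoglycan lumican, rose 39.8-fold (log2 5.32 ± 0.20 SE), while DES, the muscle filament desmin, was 2.31-fold lower. The list gave adjusted p = 0.000994, and adjusted p = 0.413 with an estimated correlation.

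Of 12 lateral plate and cardiac genes 9 rose, 2 fell and 1, GATA6, did not pass (adjusted over the list alone, also 9 and 2). HAND1, a transcription factor of heart and extraembryonic mesoderm, rose 99.5-fold, from 3.48 ± 0.96 CPM to 343.7 ± 6.82 CPM (SD, n = 2 each). Its relative HAND2 had 0 counts in BC1 and 71 and 59 under the knockout label, at least 42.8-fold higher. MYL4, an atrial light chain, was 5.99-fold lower (log2 -2.58 ± 0.29 SE). The set test gave adjusted p = 0.000994, and adjusted p = 0.29 with an estimated correlation. Of 6 HOXA genes 5 rose and 1, HOXA11, did not pass (adjusted over the list alone, also 5). HOXA7 and HOXA5 had 0 counts in BC1 and were at least 21.1-fold and 20.4-fold higher. The list's fitted median of 6.67 became 3.06 with such genes at their bound (set test adjusted p = 0.000994, and adjusted p = 0.257 with an estimated correlation).

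Epithelial genes rose in 7 of 9 cases and fell in 1 (set test adjusted p = 0.0014, and adjusted p = 0.413 with an estimated correlation), with the keratin KRT19 13.4-fold higher. CDH3 rose by a ratio of 81.0 (27.4 to 396). Of 14 amnion and trophoblast genes only 4 passed the expression filter, and all 4 rose (set test adjusted p = 0.00346, and adjusted p = 0.257 with an estimated correlation). HAND1, also on the lateral plate list, and the growth factor binding protein IGFBP3 rose the most, the latter 14.2-fold. Of 11 arterial genes 7 rose and 2 fell (set test adjusted p = 0.0147, and adjusted p = 0.593 with an estimated correlation; adjusted over the list alone, 8 rose). Of 22 Notch genes 9 rose and 1 fell (set test adjusted p = 0.0299, adjusted p = 0.629 with an estimated correlation, and adjusted p = 0.0594 with the replicate number as a block). HEY1 and HEY2, transcriptional targets of Notch, rose 4.89-fold and 3.48-fold. Like NOTCH4 and JAG1, which also rose, they are members of both the arterial and the Notch list, so these calls are not independent. The arterial genes that fell were GJA4 (log2 -0.72) and EFNB2 (log2 -0.47). Of 6 venous genes 4 fell (set test adjusted p = 0.0317, and adjusted p = 0.49 with an estimated correlation), among them the apelin receptor APLNR, 2.20-fold lower. The arterial call was lost without BC1 replicate 1 (adjusted p = 0.136) or knockout-labelled replicate 2 (adjusted p = 0.0623), the Notch call without BC1 replicate 1 (adjusted p = 0.264) and the venous call without BC1 replicate 2 (adjusted p = 0.119).

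Endothelial genes went both ways: 5 rose, 7 fell and 11 did not pass, with a median of 0.17, and 0.61 under housekeeping scaling (set test adjusted p = 0.984; adjusted over the list alone, 6 rose and 7 fell). ETV2, an early factor of blood and endothelium, rose 4.44-fold, and CLDN5, a tight junction claudin of vessels, was 2.84-fold lower. Of 22 cell cycle genes 11 fell and 2 rose (adjusted over the list alone, 12 fell). The replication licensing gene MCM2 was lower (log2 -1.43) and the proliferation antigen MKI67 higher (log2 1.36). The set test gave adjusted p = 0.0189, adjusted p = 0.264 with an estimated correlation, and adjusted p = 0.0589 with the replicate number as a block. The list's median was -0.41, but 0.03 under housekeeping scaling. Of 12 mitochondrially encoded genes 11 fell, with a median of -0.75, and -0.31 under housekeeping scaling (set test adjusted p = 0.00346, and adjusted p = 0.264 with an estimated correlation). MT-CO2, a subunit of cytochrome c oxidase, had 5488 ± 1302 CPM in BC1 and 2867 ± 60.7 CPM under the knockout label (SD, n = 2 each). MT-ND6 had 19063 and 6705 counts in BC1 and 6367 and 5496 under the knockout label. Its log2 difference of -1.09 was -0.30 without BC1 replicate 1, and it did not pass with DESeq2 (adjusted p = 0.162).

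The remaining lists did not pass. The WNT list had 4 of 10 genes up (adjusted p = 0.187), with AXIN2 4.42-fold and TNFRSF19 7.32-fold higher. The HOXB list had 4 of 7 up (adjusted p = 0.0995), with HOXB3 3.03-fold higher. In the pluripotency list ZFP42 rose 2.66-fold, DNMT3B was 2.10-fold lower and 4 genes did not pass (adjusted p = 0.69). In the hypoxia and glycolysis list 2 genes rose and 6 fell (adjusted p = 0.328), and in the immediate early list 4 rose and 1 fell (adjusted p = 0.404), with DUSP1 2.82-fold higher. Of 16 genes of the p53 list 1, SESN1, passed and fell (log2 -1.07, and -0.68 without BC1 replicate 1; set test adjusted p = 0.664). The neural list had 3 up and 1 down of 5 (adjusted p = 0.664), with a median of 0.99 but a mean of -0.51, since ZIC1 had 0 counts under the knockout label, at least 16.5-fold lower. Of 7 EGF-repeat genes related to PEAR1 only MEGF10 rose, 4.49-fold, and only STAB2 fell (set test adjusted p = 0.664). STAB2 had 42 and 35 counts in BC1 and 3 and 0 under the knockout label, a ratio of 26.0 (8.56 to 129), and its fitted log2 difference of -4.59 was -8.26 without knockout-labelled replicate 1. The endoderm list had 1 up and 1 down of 5 (adjusted p = 0.715), and 1 of 2 primitive streak genes rose.

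The BC1 libraries differed from each other the most: of genes with a mean of at least 50 counts, 15.8% differed by over 1.5-fold between them, against 0.807% between the knockout-labelled libraries, and the calls numbered 3043 and 3045 without knockout-labelled replicate 1 or 2 and 8711 and 9091 without BC1 replicate 1 or 2. The share of higher genes among the calls was 50.8% with TMM, 60.9% by library size and 81.7% by housekeeping genes, which moved the median of all genes by 0.12 and 0.44 on the log2 scale, and the cell cycle, mitochondrial and Notch lists were lost under the correction for GC content and length (adjusted p = 0.365, 0.973 and 0.291).

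The third comparison asked whether genes that marked PEAR1-positive cells were those that were lower under the knockout label. Of 2870 genes tested in both comparisons, 314 were higher in PEAR1-positive cells and lower under the knockout label, where 172 would be met by independent lists (odds ratio 3.70, 95% interval 3.06 to 4.48, Fisher's exact test, two-sided, adjusted p = 3.06e-42). Another 282 were lower in PEAR1-positive cells and higher under the knockout label, against 153 (odds ratio 3.61, 2.97 to 4.39, adjusted p = 1.57e-38). Genes that moved the same way numbered 88 up in both, against 159, and 82 down in both, against 165 (odds ratios 0.407 and 0.351, adjusted p = 9.49e-15 and 4.77e-19). Of the 766 genes called in both, 77.8% thus moved in opposite directions. The Fisher tests take genes as independent units, so their p-values and intervals do not measure the spread between samples. Across genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of -0.56 and a Spearman correlation of -0.37. For some genes BC1 lay outside both sorted populations. CDH3 had 187 and 165 counts in PEAR1-positive cells, 383 and 469 in PEAR1-negative cells, and 1 and 2 in BC1. HOXC8 had 91 and 95, 488 and 520, and 1 and 2. For these genes BC1 was no mixture of the sorted populations, so the experiments differed by more than the sort. Both were picked after seeing the values, and such genes were not counted.

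Among the genes picked by the naming rule, 39 were called in both comparisons, and 32 of them moved in opposite directions. GATA1 had log2 differences of 3.33 and -3.26, ITGA2B of 3.11 and -2.81, TYROBP of 3.03 and -3.42, and CD84 of 3.73 and -8.21. In the other direction, VCAN had -1.34 and 5.60, C5 -2.57 and 2.48, DSP -1.23 and 2.18, and BAMBI -0.95 and 1.61. The 7 that moved the same way were ACTA2, ENO1 and the replication genes E2F1, MCM2 and MCM6, all lower in PEAR1-positive cells and under the knockout label, and SEMA3G and WNT3, higher in both. WNT3 rose by a log2 of 0.53 and 0.85, and both calls were lost with DESeq2 (adjusted p = 0.151 and 0.0871). It was also lost without PEAR1-positive replicate 2 (0.45, adjusted p = 0.138), PEAR1-negative replicate 2 (0.46, adjusted p = 0.0823), or knockout-labelled replicate 1 or 2 (0.87 and 0.83, adjusted p = 0.138 and 0.165). With a log2 fold change of at least 1 asked in both, 197 genes were shared and 94.4% of them moved in opposite directions. The shared calls numbered 432 and 428 without knockout-labelled replicate 1 or 2 and 1170 without BC1 replicate 2, of which 84.0%, 84.6% and 67.9% moved in opposite directions.

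**Figure D3:**
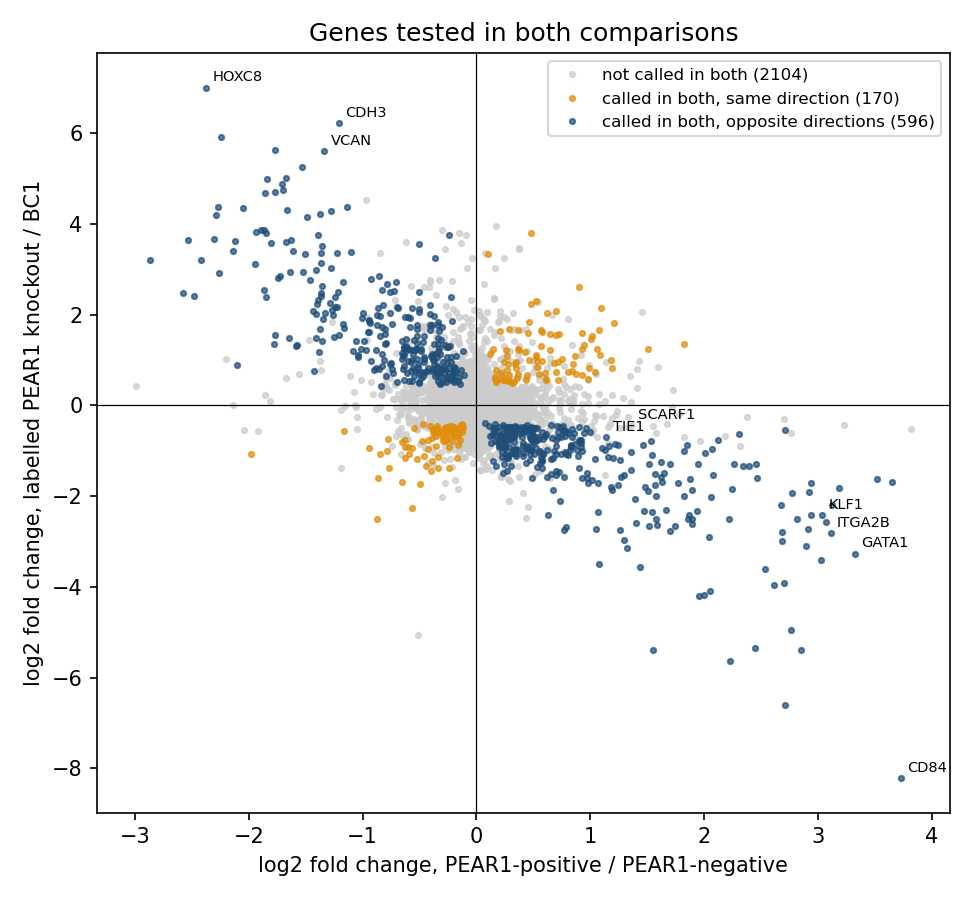
Each point is one of the 2870 genes tested in both comparisons, placed by its log2 fold change between the sorted populations (horizontal axis) and between the lines (vertical axis, with genes at 0 in one line at the bound set by 3 counts). The 596 genes called in both with opposite directions lie at the upper left and lower right, and 170 moved the same way.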

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

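The correction for GC content and length, the crossed pairing, the fit to genes held in both tables and the housekeeping scaling of the overlap were chosen after seeing the data. A log2 fold minimum of 1 left 315 of the 1535 calls in the sorted cells, 3209 of the 5812 in the lines and 197 of the 766 genes called in both, by construction. The calls ranged from 1288 to 1447 in the sorted cells and from 3043 to 9091 in the lines when 1 library was left out, where the lone library of an arm is assumed to vary like the other group. The genes called in both ranged from 428 to 1170, and 67.9% to 84.6% of them moved in opposite directions. DESeq2 called 1060 and 4855 genes, and the correction for GC content and length 1583 and 7312. With the genes held in both tables alone, 42.1% of genes passed between the lines.

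Of the lists, 8 passed in the sorted cells and 17 in the lines. With an estimated correlation 0 and 0 passed by adjusted p, and 1 and 4 at an unadjusted p under 0.05. Fry called 14 and 18 lists in one direction and 17 and 26 in either, a test that does not compare a list with other genes. The lists numbered 9 to 10 and 15 to 17 with 1 library left out.

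The replicate numbers showed no sign of pairing: deviations of equally numbered libraries correlated at 0.06 in the sorted cells and -0.18 in the lines. With 2 libraries per group this cannot exclude that equally numbered samples were handled together. With the replicate block 1547 and 5596 genes and 8 and 15 lists were called, and 727 genes in both, of which 78.4% moved in opposite directions; the cell cycle and Notch lists of the lines were lost (adjusted p = 0.0589 and 0.0594). The crossed pairing called 6485 genes.

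For single named genes no direction of a called gene turned. In the sorted cells 483 values stayed on their side of the threshold and 7 lost it. In the lines 708 stayed, 28 lost it and 1, PEAR1 without BC1 replicate 2, gained it. The causes were not tested. Depth limits what can be said of genes under about 10 counts in a library; the sorted cells are limited further by the extent of their table.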

Other observations

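The tests of lists in this paragraph, the test of mesenchymal against endothelial genes and the count of knockout groups below were chosen after the results were seen. The camera p-values in this paragraph were not adjusted and, for lists chosen in this way, only describe these data. With an estimated correlation, 4 of the 27 fixed lists of the lines also had an unadjusted p below 0.05, and 0 passed after adjustment. Interferon-stimulated genes, which cells use against viruses, were lower under the knockout label: of 27 tested, 18 fell and 1, IFI27, rose, with a median log2 of -1.37 (camera p = 1.69e-07, and p = 0.0278 with an estimated correlation). MX1, an antiviral GTPase, had 372 and 373 counts in BC1 and 9 and 10 under the knockout label (39.4-fold lower, adjusted p = 2.11e-05). OAS1, OAS2 and OAS3, sensors of double-stranded RNA, were 33.4-fold, 20.1-fold and 7.94-fold lower, and ISG15 3.15-fold. In the sorted cells OAS1 was the only member tested, with a log2 difference of -0.51 that did not pass (adjusted p = 0.46). Of the HOXC cluster, 4 genes were tested and all rose under the knockout label, by a median log2 of 4.81 with genes at 0 in BC1 at their bound (camera p = 9.59e-05, and p = 0.0679 with an estimated correlation). HOXC6 had 8 and 1 counts in BC1 and 207 and 188 under the knockout label (42.5-fold higher). HOXC8 had 1 and 2 against 208 and 215, and in the sorted cells it was 5.18-fold lower in PEAR1-positive cells (adjusted p = 5.67e-74).

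Median log2 differences of genes with a mean log2 CPM of at least 3 lay between -0.25 and 0.11 for every autosome between the lines, chromosomes 22 and 13 being the ends of that range.

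Most tested genes of the blood lists were lower under the knockout label, and most of the mesenchymal and matrix lists higher. A bias of GC content or gene length as the whole cause is argued against by the 64 tested blood genes, whose median of -1.84 was -1.74 after the correction (interquartile range -3.36 to -1.19). A loss of blood cells from an otherwise unchanged culture would raise the other cell types alike, if their lists held no genes of the lost cells. The mesenchymal and endothelial medians of 1.61 and 0.17 lay 1.44 apart (permutation test over 14 and 23 genes, which are not independent, two-sided, p = 0.00118). This cannot decide the question, because 4 of 5 tested endothelial genes were higher in PEAR1-positive cells and 1 was lower, while most tested blood genes were higher there too. A loss of blood cells and a change within the other cells both stay open. The loss of PEAR1 and any other difference between the lines or their cultures cannot be told apart, because 1 knockout group stands beside 1 parent and the difference in PEAR1 transcript did not pass the test.

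The fold changes of the comparisons ran in opposite directions across genes. With GC content, length and expression level removed from both, the Spearman correlation was -0.35, against -0.37 before, which argues against these as the whole cause. It was -0.36 over the 2790 of 2870 genes outside every fixed list, so the list members alone do not carry it. Few genes were thereby left out, so this cannot decide whether blood and mesenchymal genes outside the lists carry it. Whether PEAR1-positive cells held most of the blood-forming cells, and these were fewer under the knockout label, stays open and was not tested apart from a direct effect of PEAR1.

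Some autosomal genes had at least 10 counts in each library of one line and 0 in both of the other: 24 in BC1 alone and 28 under the knockout label alone. A fixed difference between the lines, unrelated to PEAR1 on the surface, was taken beforehand to leave such genes without a preferred sign in the sorted cells. Of the 5 that were tested there, PITX1, PITX3, HOXA3, HOXA5 and HOXA6, 100% had the opposite sign (exact 95% interval 47.8% to 100%, exact binomial test, two-sided, p = 0.0625, the smallest that 5 genes can give). That number is too small to decide, 3 of the 5 lie in one cluster, and none of the genes counted in BC1 alone, such as TSPYL5, NLRP2 and ALDH1A1, was among them. More genes would not decide it either, because equal signs are not what other genes showed. Among genes called in both and higher under the knockout label, 282 were lower in PEAR1-positive cells and 88 higher.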
